A study of Arabidopsis thaliana with 9 samples.

How the data were processed

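Polyadenylated RNA of whole Arabidopsis thaliana seedlings was sequenced in 9 libraries, 3 each of the wild type Col and of the mutants csu5-1 and csu5-3, all grown for 5 days in constant white light at 14.59 μmol per square metre and second, per the labels' protocols. Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned to TAIR10 with HISAT2 2.05 and counted per gene with HTSeq. The deposited files give 1 value per gene and library for 32678 genes, with no header and no stated unit. The deposited values were read as FPKM (fragments per kilobase of exon and per M counted reads), from the values themselves: the FPKM sums of the libraries lay between 691388 and 718744 and differed from each other, and low values of short genes (exon length 60 to 450 bases) were whole multiples of what 1 read is worth. How the authors made the FPKM from the counted reads is not given in the sources used here, and RPKM and FPKM could not be told apart.

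The steps between low values gave each library's depth. At 37.2 to 43.1 M counted reads, 75.4% to 79.8% of the 317 to 348 low values used per library came within 0.1 read of a whole number, against 16.4% to 18.0% at other depths. One read on a gene of 1 kilobase was then worth 0.0232 to 0.0269 FPKM. Replicate pairs differed by more than counting error, with a mean chi-square per gene of 8.15 to 13.23, so no library was a copy of another.

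Gene names came from the RefSeq table of the TAIR10.1 assembly, which matched 31912 of the 32678 identifiers. The authors aligned to TAIR10, so no coordinates are given, and TAIR10.1 served only for names, products, neighbours, exon lengths and GC content. The notes do not say whether counting used strand, so values of genes that overlap another annotated gene are uncertain. Of the 159 genes named under the rule below, 147 could be placed in TAIR10.1 and the others were not checked for overlap. Of the 147, 33 overlap another gene (among them FLC, LHCB2.3, LHCB4.2, PSAH2, CAO, CHS, TT19, BBX24, BBX25, LNK1, LNK2, LOX1, DIR1 and CPD). Genes with near-identical copies (LHCB2, the AT4G15660 to AT4G15700 cluster and SAUR19 to SAUR24) can share reads and are likewise uncertain. Of the 100-base windows of each LHCB1 copy, 95.6% to 98.5% occur in no other LHCB1 copy.

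The test planned before the data were examined was for read counts. Because the values were FPKM, limma 3.58.1 in R 4.3.3 was used instead, on log2(FPKM + 0.5), with a mean-variance trend. Each library was scaled by a mean of its log ratios to the average library, trimmed by a share of 0.3 at each end. The scaling factors were 1.017 to 1.025 for Col, 0.9611 to 0.9697 for csu5-1 and 1.011 to 1.028 for csu5-3. Genes with at least 1 FPKM in at least 3 libraries were tested, 19329 in all. One model with a mean per genotype was fitted to the 9 libraries, and the 3 comparisons were csu5-1 against Col, csu5-3 against Col and csu5-1 against csu5-3. A gene was called at a Benjamini-Hochberg adjusted p below 0.01 and a fold above 1.5 in either direction, the thresholds the series text states. Fold changes are on the log2(FPKM + 0.5) scale, which understates changes of low genes. "Rose" and "fell" are used only for called genes and lists. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the plots.

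The 22 gene lists were fixed before the data were examined, 20 by gene (460 entries) and 2 as all genes encoded in the chloroplast or the mitochondrion. They cover the light-harvesting antenna, photosystems and carbon fixation, chlorophyll synthesis, flavonoid and anthocyanin synthesis, light regulators, auxin, cell elongation and PIF targets, brassinosteroid, gibberellin, the circadian clock, salicylic acid and immunity, jasmonate, abscisic acid with drought and cold, heat shock, glucosinolates, cytokinin type-A response regulators, iron deficiency, root markers, stomatal lineage and guard cells, and seed reserves and embryo. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over all 66 tests and called below 0.05. An estimated correlation and limma's fry were the alternatives. Camera compares a list's genes with all other genes, whereas fry asks whether the list's genes change at all. Their calls thus answer different questions. A list's count is also given adjusted over the list alone.

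The genes named were fixed by a rule. In each comparison these were the 10 called genes with the largest rise and the 10 with the largest fall, among those with a mean of at least 2 (in FPKM here) whose 3 libraries of one genotype all lay on one side of the other's. For each list they were the called members with the 4 smallest p-values, or the 2 smallest where none was called. The 5 leading genes called in the same or in opposite directions in both mutants were added, and HY5, PIF4, COP1, CHS and BBX21 to BBX32 could always be named. Other named genes are said to be chosen after their values were seen.

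The test was tried on simulated data with the real genes and means, and with independent noise of the spread limma estimated per gene. Noise shared between genes was left out. For 19329 genes and the design of csu5-1 against Col the test recovered 87% of genes changed 2-fold and 100% of those changed 4-fold with 1 false call. For csu5-3 against Col it recovered 87% and 99% with 0 false calls. Because both mutants share the Col libraries, 100 simulations of unchanged mutants gave the covariance of fold changes that shared controls alone produce. The alternatives tried were median-ratio scaling, no scaling, no filter, a filter of 5 FPKM, other thresholds, limma's treat, fits to the 6 libraries compared, the replicate number as a block, and each library left out. Alternatives added after the data were seen were pseudocounts of 0.1 and 1, quantile normalization, limma without the trend, and removal of trends on exon length and GC content. The planned count-based tests other than limma's were not run because the values are not counts. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.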

Results

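RNA was sequenced from whole seedlings of 3 Arabidopsis thaliana genotypes, each 5 days old and grown in constant white light at 14.59 μmol per square metre and second, with 3 libraries per genotype. Col is the wild-type Columbia accession. The mutants csu5-1 and csu5-3 carry changes in a gene the series calls COP1 SUPPRESSOR 5. COP1 is a ubiquitin ligase that represses light-driven seedling development (photomorphogenesis). The series title speaks of a missense mutation with a reversed action, and the labels do not say which allele it is. The estimated depth was 39.9, 42.0 and 39.4 M counted reads in the Col libraries, 37.6, 37.2 and 39.7 M in csu5-1, and 43.1, 40.7 and 39.1 M in csu5-3. Between 22643 and 22784 genes had a value above 0. Across all tested genes, the first principal component (66.9% of the variance) put the csu5-1 libraries at 45.7 to 49.1 and the other 6 libraries at −26.1 to −22. The second (8.91%) put Col at 9.88 to 20.1 and csu5-3 at −17.7 to −11.5. Values below are mean FPKM ± SD over n = 3 libraries, as deposited and before scaling. Fold changes are log2 ± SE from limma on the scaled values, with Benjamini-Hochberg adjusted p. They can therefore differ from the ratio of the printed means.

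No locus for the mutated gene is given in the sources used here. Background knowledge outside the labels points to WRKY32 (AT4G30935), a WRKY-family transcription factor, an identity that was not checked here. WRKY32 stood at 8.48, 10.06 and 11.08 FPKM in the Col libraries, 8.17, 8.22 and 7.96 in csu5-1, and 4.58, 3.65 and 3.78 in csu5-3. It fell in csu5-3 against Col (log2 fold −1.20 ± 0.12, adjusted p = 0.00057) and was below every Col library in all 3 csu5-3 libraries. In csu5-1 its log2 fold against Col was −0.18 ± 0.12 (adjusted p = 0.21), and csu5-1 exceeded csu5-3 (1.02 ± 0.12, adjusted p = 1.6e-05). RNA level does not show whether either allele changes the protein.

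The comparison of csu5-1 with Col asked how this allele changed gene expression in light-grown seedlings. Of 21 genes of the light-harvesting antenna, the proteins that hold chlorophyll around the photosystems, 16 rose in csu5-1 and 1, the most abundant (LHCB1.3), fell (list adjusted p = 0.082 with an estimated correlation). LHCB2.3 (AT3G27690) went from 90.3 ± 2.34 FPKM in Col to 1490 ± 30.9 in csu5-1, LHCB2.1 (AT2G05100) from 292 ± 4.43 to 2810 ± 75.5, and LHCB2.2 (AT2G05070) from 236 ± 16.2 to 2740 ± 122. PORA (AT5G54190), an enzyme that makes chlorophyllide in light and is classically abundant in dark-grown seedlings, rose from 1.58 ± 0.404 to 125 ± 15.6 FPKM (log2 fold 6.0 ± 0.19, adjusted p = 4.5e-10). FLC (AT5G10140), a repressor of flowering, fell from 23 ± 1.16 to 0.717 ± 0.388 FPKM (log2 fold −4.27 ± 0.19, adjusted p = 5.5e-09). In all, 1606 genes rose and 1519 fell among 19329 tested, 16.2% of them, and 118 rose and 36 fell by more than 4-fold. Without scaling, 1313 rose and 1962 fell, since the median gene then lay at −0.08 in csu5-1.

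Of the 21 antenna genes tested, 16 rose, 1 fell and 4 did not pass (16 and 1 adjusted over the list alone), with a median log2 fold of 1.33 (camera adjusted p = 1.6e-13, adjusted p = 0.082 with an estimated correlation). LHCB4.2 (AT3G08940) rose from 802 ± 18.9 to 1900 ± 31.3 FPKM. The 1 antenna gene that fell was LHCB1.3, chosen here after its values were seen, from 38700 ± 1290 to 24000 ± 206 FPKM (−0.61 ± 0.12, adjusted p = 0.0015). LHCB1.3 was not called without csu5-1 replicate 1 (adjusted p = 0.01), with no filter on low values (adjusted p = 0.30) or after removal of exon length and GC trends (log2 fold −0.56), and quantile normalization sets its fold to 0 because it was the most abundant gene in every library. Chlorophyll synthesis also rose as a list, with 7 of 20 members higher and 2 lower (7 and 2 adjusted over the list alone), a median of 0.32 and adjusted p = 0.0044 (adjusted p = 0.48 with an estimated correlation). Its members CAO (AT1G44446), which makes chlorophyll b, and CHLH (AT5G13630), a subunit of magnesium chelatase, rose from 69.2 ± 6.23 to 185 ± 3.14 FPKM and from 205 ± 11.3 to 416 ± 26.9 FPKM. GLK1 (AT2G20570), a transcription factor that activates photosynthesis genes, fell from 68.1 ± 1.6 to 33.1 ± 3.11 FPKM. Among 37 genes of the photosystems and carbon fixation, 8 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.38 and adjusted p = 1.7e-05 (adjusted p = 0.35 with an estimated correlation), a median that quantile normalization turned to −0.08 (adjusted p = 0.90). PSBW (AT2G30570), a photosystem II subunit, rose from 811 ± 12.1 to 1500 ± 19 FPKM, and RBCS1B (AT5G38430), a small subunit of the CO2-fixing enzyme Rubisco, fell from 839 ± 14.2 to 365 ± 6.34 FPKM. PSBY (AT1G67740) and PSAH2 (AT1G52230) rose with log2 folds of 0.79 ± 0.06 and 0.86 ± 0.05, and PSBW and PSAH2 were not called under quantile normalization (log2 folds 0.57 and 0.50). Of 90 chloroplast-encoded genes, 2 rose and 18 fell (2 and 15 adjusted over the list alone), with a median of −0.35 and adjusted p = 0.014 (adjusted p = 0.60 with an estimated correlation). That list's adjusted p was 0.07 without Col replicate 3 and 0.084 without scaling. Chloroplast transcripts are mostly not polyadenylated, so their values depend on how poly(A) selection went, and their summed FPKM was 722.5 ± 75.3 in Col, 440.6 ± 44.8 in csu5-1 and 679.6 ± 125 in csu5-3.

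Of 20 tested genes of the flavonoid and anthocyanin pathway, 12 rose, 1 fell and 7 did not pass (12 and 1 adjusted over the list alone), with a median of 0.89 (adjusted p = 2.3e-05, adjusted p = 0.10 with an estimated correlation). CHS (AT5G13930), the first enzyme of the pathway, rose from 3.2 ± 0.459 to 32.8 ± 4.03 FPKM (3.24 ± 0.12). DFR (AT5G42800), a later enzyme, was listed at 0 in all 3 Col libraries and at 5.32 ± 1.42 FPKM in csu5-1. TT19 (AT5G17220), needed to store anthocyanin, rose from 0.0633 ± 0.0651 to 10.7 ± 1.19 FPKM, and MYBL2 (AT1G71030), a repressor of anthocyanin genes, fell from 14 ± 0.593 to 5.1 ± 0.313 FPKM. Without csu5-1 replicate 1, 2 or 3 this list's adjusted p was 0.068, 0.055 and 0.068, because only 12 of its genes then passed the filter on low values. The other 8 passed it through the csu5-1 libraries alone and all rose, so the count and the call of this list rest in part on genes admitted by their own rise. Of the 12, 4 rose and 1 fell. In other lists, rises of genes that passed through csu5-1 alone numbered 2 in light regulators and 2 in jasmonate. There was 1 each in elongation, gibberellin, salicylic acid and abscisic acid.

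Of 24 tested genes of cell elongation and targets of the PIF transcription factors, 18 rose and 0 fell (19 and 0 adjusted over the list alone; 0 fell at an unadjusted p below 0.05 in limma), with a median of 0.99 (adjusted p = 5e-10, adjusted p = 0.081 with an estimated correlation). The expansins EXPA8 (AT2G40610) and EXPA11 (AT1G20190) rose from 51 ± 4.24 to 155 ± 11.2 FPKM and from 67.9 ± 6.47 to 155 ± 8.13 FPKM. The wall enzyme gene XTH17 (AT1G65310) rose with a log2 fold of 1.61 ± 0.07, and PRE6 (AT1G26945), a small helix-loop-helix regulator of growth, with 2.27 ± 0.10. Of 31 auxin genes, 12 rose and 0 fell (13 and 0 adjusted over the list alone; 1 fell at an unadjusted p below 0.05 in limma), with a median of 0.47 (adjusted p = 1e-06, adjusted p = 0.14 with an estimated correlation). YUC8 (AT4G28720), an enzyme of auxin synthesis, rose from 2.48 ± 0.296 to 9.09 ± 0.716 FPKM, and the auxin-induced IAA19 (AT3G15540) from 4.61 ± 1.12 to 18.7 ± 0.69 FPKM. SAUR22 (AT5G18050) and SAUR19 (AT5G18010), small auxin-induced genes, rose with log2 folds of 1.79 ± 0.18 and 1.61 ± 0.16. Among 13 gibberellin genes, 5 rose (5 adjusted over the list alone), with a median of 0.12 (adjusted p = 0.022, adjusted p = 0.14 with an estimated correlation, and 0.06 without csu5-1 replicate 3). GA3OX1 (AT1G15550), which makes active gibberellin, and GA2OX6 (AT1G02400), which breaks it down, rose with log2 folds of 2.53 ± 0.16 and 1.45 ± 0.09, as did RGL1 (AT1G66350, 1.27 ± 0.09) and GAI (AT1G14920, 0.66 ± 0.06), repressors of gibberellin signalling. Without scaling GAI was not called (0.58).

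Of 12 brassinosteroid genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone), with a median of 0.25 and adjusted p = 0.044 (adjusted p = 0.25 with an estimated correlation). BR6OX1 (AT5G38970), a synthesis enzyme, rose with 1.06 ± 0.12 and BAS1 (AT2G26710), which inactivates the hormone, with 0.82 ± 0.09. ROT3 (AT4G36380) rose with 0.63 ± 0.06 (not called without scaling, 0.55), and CPD (AT5G05690) fell with −0.61 ± 0.05 (not called without csu5-1 replicate 2, −0.56, or under quantile normalization, −0.54). The brassinosteroid list's adjusted p was 0.052 without Col replicate 1, 0.05 without Col replicate 3, 0.053 without csu5-1 replicate 1 and 0.05 without csu5-3 replicate 3. Of 10 genes of the stomatal lineage and guard cells, 5 rose (5 adjusted over the list alone), with a median of 0.58 and adjusted p = 0.022 (adjusted p = 0.14 with an estimated correlation, and 0.10 at a filter of 5 FPKM). TMM (AT1G80080), a receptor that patterns stomata, rose from 9.7 ± 1.14 to 22 ± 2.57 FPKM, and SPCH (AT5G53210), which starts the lineage, from 4.21 ± 0.24 to 6.81 ± 0.706 FPKM. BASL (AT5G60880), a polarity gene of that lineage, and KAT1 (AT5G46240), a guard cell potassium channel, rose with 1.15 ± 0.20 and 1.17 ± 0.10.

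Regulators of the light response changed as well. Of 45 tested, 14 rose, 1 fell and 30 did not pass (14 and 1 adjusted over the list alone), with a median of 0.37 (adjusted p = 0.00017, adjusted p = 0.081 with an estimated correlation). PIF5 (AT3G59060) and PIF4 (AT2G43010), which promote elongation in shade and darkness, rose from 14.5 ± 1.15 to 59.6 ± 1.95 FPKM and from 16.9 ± 1.35 to 56 ± 4.25 FPKM. The B-box genes BBX24, BBX25, BBX28, BBX30, BBX31 and BBX32 rose with log2 folds of 0.95 to 2.41, and the photoreceptor gene PHYA (AT1G09570) with 0.99 ± 0.06. HY5 (AT5G11260), the central activator of photomorphogenesis, had a log2 fold of −0.56 ± 0.09 (adjusted p = 0.00026), below the fold threshold. COP1 (AT2G32950) had a log2 fold of 0.10 ± 0.06 (adjusted p = 0.21). BBX21 stood at −0.03 ± 0.06 (adjusted p = 0.70).

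Clock genes moved both ways. Of 30 tested, 9 rose, 10 fell and 11 did not pass (10 and 10 adjusted over the list alone). The median was −0.03, the mean 0.13, and camera's direction was up with adjusted p = 0.76. LHY (AT1G01060) and CCA1 (AT2G46830), whose proteins peak at dawn in wild-type plants, rose from 21.3 ± 1.83 to 102 ± 0.531 FPKM and from 17 ± 2.86 to 83.2 ± 2.92 FPKM, and their co-regulated partners LNK1 (AT5G64170) and LNK2 (AT3G54500) with log2 folds of 2.07 ± 0.11 and 2.46 ± 0.07. Chosen after their values were seen, the evening genes TOC1 (AT5G61380) and ELF4 (AT2G40080) fell with −0.78 ± 0.06 and −1.27 ± 0.11, and the clock-driven RNA-binding gene GRP7 (AT2G21660) from 2110 ± 248 to 833 ± 19.2 FPKM. No hour of collection is given in the sources used here.

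**Figure D1:**
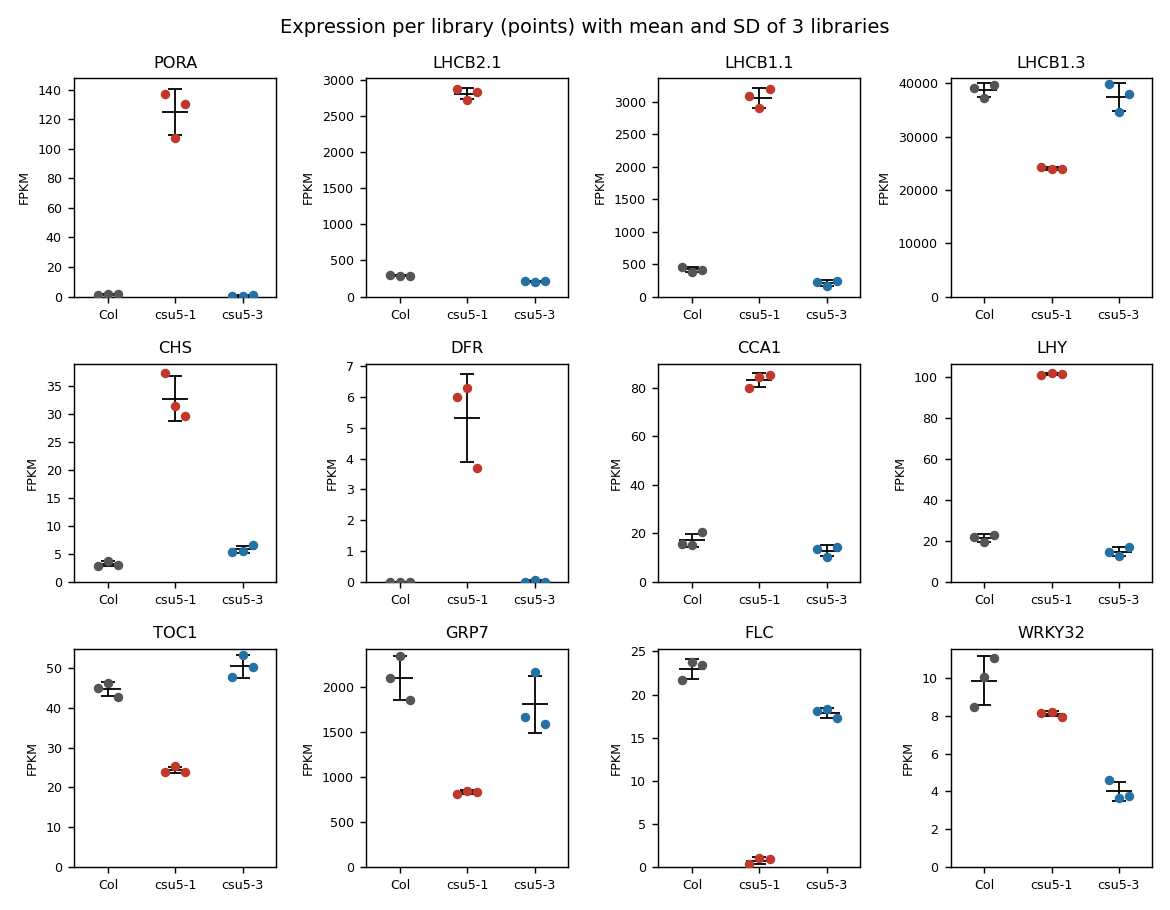
FPKM of 12 genes in each of the 9 libraries, by genotype, with the mean and SD over 3 libraries (each panel has its own axis). PORA rose from 1.58 in Col to 125 in csu5-1, LHCB1.3 fell from 38700 to 24000 (its fold is 0 under quantile normalization), FLC fell from 23 to 0.717, and WRKY32 fell in csu5-3 (log2 fold −1.20); LHCB1.3, TOC1, GRP7 and the panel layout were chosen after the values were seen.

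The genes with the largest rise in csu5-1 under the naming rule also held ALMT1 (AT1G08430), a malate channel, THI2.2 (AT5G36910), a thionin, SULTR3;5 (AT5G19600), a sulfate transporter, RTFL18 (AT5G16023), AT2G47780, AT5G44440 and AT5G03350, with log2 folds of 3.61 to 4.11. The genes with the largest fall held AT1G23130, CRL2 (AT2G33600), AT1G30250, AT3G01345 and 5 genes annotated as thioredoxin superfamily proteins, AT4G15660, AT4G15670, AT4G15690, AT4G15700 and AT5G18600, with log2 folds of −3.86 to −2.97. The other lists were not called. Of 9 cytokinin type-A response regulators 4 fell (4 adjusted over the list alone; median −0.38, adjusted p = 0.065). ARR4 (AT1G10470) went from 110 ± 1.89 to 51.9 ± 5.46 FPKM, and ARR6, ARR7 and ARR3 fell with −0.73 ± 0.08, −1.06 ± 0.12 and −0.69 ± 0.17. Without Col replicate 1 or 2, or csu5-1 replicate 1 or 3, ARR3 was not called (−0.67, −0.55, −0.60 and −0.72). Of 17 root markers 1 rose and 7 fell (1 and 7 adjusted over the list alone; median −0.43, adjusted p = 0.085). The root-hair wall gene PRP3 (AT3G62680) fell from 20.3 ± 2.63 to 6.74 ± 0.89 FPKM, EXPA18 with −1.18 ± 0.15 and PRP1 with −1.76 ± 0.23, whereas SHR (AT4G37650), a regulator of root patterning, rose with 0.62 ± 0.07 (not called without Col replicate 3, 0.58, or without scaling, 0.54).

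Of 15 salicylic acid and immune genes 3 rose (3 adjusted over the list alone; median 0.28, adjusted p = 0.11): ICS1 (AT1G74710), which makes salicylic acid, WRKY40 and CBP60G, with 1.49 ± 0.12, 0.95 ± 0.19 and 1.06 ± 0.21. Of 19 jasmonate genes 4 rose and 3 fell (4 and 3 adjusted over the list alone, median 0.16, adjusted p = 0.13). Of these genes 3 passed the filter on low values through csu5-1 alone, and 2 of them rose. Of the other 16, 2 rose and 3 fell, with a median of 0.05. VSP2, AOS and LOX4 rose with 2.68 ± 0.11, 0.89 ± 0.07 and 1.31 ± 0.17, and JAZ9 fell with −0.80 ± 0.09. Of 28 genes of abscisic acid, drought and cold 2 rose and 4 fell (2 and 4 adjusted over the list alone; median −0.07, adjusted p = 0.81). CBF2 and RD20 rose with 2.03 ± 0.19 and 1.17 ± 0.17, and RD26 and ABI5 fell with −0.87 ± 0.08 and −0.72 ± 0.14. Of 8 heat shock genes 1 fell, HSP70 (AT3G12580, −0.66 ± 0.10, not called without Col replicate 3, −0.58; list adjusted p = 0.27). Of 16 glucosinolate genes 1 rose, MYB28 (AT5G61420, 0.78 ± 0.08), with a median of 0.03, a mean of −0.04, camera's direction up and adjusted p = 0.50. Of 8 seed reserve and embryo genes 2 rose, MLS (AT5G03860) and ICL (AT3G21720), the glyoxylate cycle enzymes that turn stored fat into sugar, with 1.95 ± 0.09 and 2.71 ± 0.20. That list's median was −0.22, its mean 0.33, camera's direction up and adjusted p = 0.59. Of 13 iron deficiency genes 0 were called by limma (3 were lower at an unadjusted p below 0.05; adjusted p = 0.40), with OPT3 and FRO3 at −0.55 ± 0.06 and −0.58 ± 0.07. Of 12 mitochondrion-encoded genes 4 fell (3 adjusted over the list alone; adjusted p = 0.23), of which ATMG01390 (−0.80 ± 0.22, adjusted p = 0.0096) lost its call without any 1 of the Col or csu5-1 libraries (−0.93 to −0.69) or csu5-3 replicate 2, and ATMG00990 (−1.31 ± 0.30) without Col replicate 1 (−1.10).

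The comparison of csu5-3 with Col asked the same for the other allele. Few genes passed the test: 23 rose and 25 fell among 19329 tested, against 4250 at an unadjusted p below 0.05. BGLU18 (AT1G52400), a beta-glucosidase that releases abscisic acid from its glucose ester, rose from 3.6 ± 0.498 to 12.8 ± 4.34 FPKM (log2 fold 1.64 ± 0.18, adjusted p = 0.0012), and LOX1 (AT1G55020), a lipoxygenase, from 13.7 ± 1.39 to 25.4 ± 0.679 FPKM (0.87 ± 0.08, adjusted p = 0.00057). AT1G52000, a mannose-binding lectin gene, rose from 7.14 ± 1.53 to 27.2 ± 8.54 FPKM. Besides WRKY32, AT3G01345 fell from 13.6 ± 5.19 to 0.253 ± 0.15 FPKM (−4.15 ± 0.40, adjusted p = 0.00057), and the auxin-induced IAA2 (AT3G23030) from 69.3 ± 6.53 to 41.3 ± 4.33 FPKM (−0.74 ± 0.08, adjusted p = 0.0011).

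DIR1 (AT5G48485), a lipid-transfer protein of systemic resistance, fell from 64.1 ± 5.05 to 35.7 ± 2.34 FPKM, and AT1G22690 and AT4G25580 with −1.37 ± 0.15 and −1.12 ± 0.13. These genes, BGLU18, LOX1, AT1G52000, WRKY32, AT3G01345 and IAA2 kept their calls with any 1 library left out. With no filter on low values, BGLU18 (adjusted p = 0.015), AT1G22690 (0.016), AT1G52000, AT3G01345, AT4G25580 and IAA2 (0.01 each) were not called. Without limma's trend, LOX1 (0.011), AT3G01345 (0.012), AT1G52000 (0.015), BGLU18 and IAA2 (0.021 each) and AT1G22690 (0.023) were not. WRKY32 and DIR1 kept their calls in both settings, in which 9 and 5 genes were called in all. The cold-induced COR15A (AT2G42540) rose from 18.5 ± 2.53 to 56.2 ± 16.6 FPKM and the jasmonate-induced CORI3 (AT4G23600) from 2.92 ± 0.535 to 6.99 ± 0.996 FPKM. COR15A was not called without Col replicate 1 or 3 or csu5-3 replicate 1 or 2 (adjusted p = 0.012, 0.012, 0.011 and 0.01), nor CORI3 (0.018, 0.012, 0.016 and 0.019). LHCB1.1 (AT1G29920) fell from 418 ± 35.9 to 211 ± 41.1 FPKM and the transposon-derived SADHU3-2 (AT3G42658) with −1.47 ± 0.16. Both lost their calls without Col replicate 1 (adjusted p = 0.012 and 0.01). CP1 (AT4G36880), ESP (AT1G54040), AT5G44400, AT2G46640 and AT1G75550 rose with log2 folds of 0.81 to 1.06, and AT2G41550, AT1G22890 and KCS12 fell with −0.97 to −0.86. Each of those 8 lost its call without Col replicate 1 and without csu5-3 replicate 2 (adjusted p = 0.012 to 0.044), and some without other libraries.

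Of the gene lists, 4 rose and 5 fell in csu5-3 by camera, most with few or no called members. With an estimated correlation 0 were called (lowest adjusted p = 0.086, 3 of 22 at an unadjusted p below 0.05). Fry also called 9, but not the same lists. It called light regulators (adjusted p = 0.032), stomatal lineage (0.023) and gibberellin (0.0015) in place of abscisic acid (0.061), photosystems (0.12) and flavonoids (0.074). Of 19 jasmonate genes 1 rose, CORI3 (4 adjusted over the list alone), with a median of 0.30 (adjusted p = 1.2e-05, adjusted p = 0.14 with an estimated correlation). Of 16 glucosinolate genes 0 were called by limma (9 higher at an unadjusted p below 0.05; 0 adjusted over the list alone), with a median of 0.33 (adjusted p = 1.2e-05, adjusted p = 0.33 with an estimated correlation). MYB28 and UGT74C1 stood at 0.43 ± 0.08 and 0.31 ± 0.06. Of 28 genes of abscisic acid, drought and cold 2 rose, COR15A and RD22 (AT5G25610, 0.60 ± 0.07; 2 adjusted over the list alone), with a median of 0.19 (adjusted p = 2.3e-05, adjusted p = 0.33 with an estimated correlation). RD22 was not called without Col replicate 1 (0.50) or csu5-3 replicate 2 (adjusted p = 0.011). Of 20 flavonoid genes 1 rose, CHS, from 3.2 ± 0.459 to 5.78 ± 0.667 FPKM (1 adjusted over the list alone), with a median of 0.14 (adjusted p = 0.044, adjusted p = 0.33 with an estimated correlation). CHS was not called without Col replicate 1 or 3, csu5-1 replicate 2 or 3, or csu5-3 replicate 1, 2 or 3 (adjusted p = 0.034, 0.022, 0.011, 0.012, 0.016, 0.018 and 0.025). The flavonoid list's adjusted p was 0.093 without Col replicate 1 and 0.05 without csu5-3 replicate 3.

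The antenna list fell in csu5-3, with LHCB1.1 called among 21 (0 rose, 1 fell; 0 and 1 adjusted over the list alone) and a median of −0.13 (adjusted p = 1.2e-05, adjusted p = 0.21 with an estimated correlation). Of 31 auxin genes 1 fell, IAA2 (2 adjusted over the list alone), with a median of −0.23 (adjusted p = 0.00012, adjusted p = 0.25 with an estimated correlation). Of 30 clock genes 0 were called by limma (9 lower and 2 higher at an unadjusted p below 0.05; 0 adjusted over the list alone), with a median of −0.19 (adjusted p = 0.004, adjusted p = 0.086 with an estimated correlation) and LHY at −0.53 ± 0.10. Of 13 iron deficiency genes 0 were called by limma (6 lower at an unadjusted p below 0.05; 1 lower adjusted over the list alone), with a median of −0.23 (adjusted p = 0.0048, adjusted p = 0.16 with an estimated correlation, and 0.15 at a filter of 5 FPKM). IMA2 and FRO3 stood at −1.33 ± 0.32 and −0.31 ± 0.07. Of 37 genes of the photosystems and carbon fixation 0 were called by limma (9 lower at an unadjusted p below 0.05; 0 adjusted over the list alone), with a median of −0.05 (adjusted p = 0.022, adjusted p = 0.60 with an estimated correlation), which quantile normalization turned to 0.01 (adjusted p = 0.92). Without csu5-3 replicate 2 or 3 that list's adjusted p was 0.15 and 0.10.

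The other 13 lists were not called by camera in csu5-3: chlorophyll synthesis (adjusted p = 0.13), light regulators (0.16), stomatal lineage (0.19), seed reserve (0.33), gibberellin (0.36), cell elongation (0.40), salicylic acid (0.50), brassinosteroid (0.52), root markers (0.60), cytokinin regulators (0.61), heat shock (0.61), mitochondrion-encoded (0.82, median −0.10, mean 0.02, camera's direction down) and chloroplast-encoded genes (0.99, median 0.01, mean −0.01, camera's direction up). Their 1 called member was the expansin EXPA4 (AT2G39700), up from 30.1 ± 4.46 to 47.3 ± 2.37 FPKM, which lost its call without Col replicate 1 or 3 or csu5-3 replicate 1 or 2 (adjusted p = 0.015, 0.013, 0.011 and 0.016), with no filter (0.021), without limma's trend (0.037) and with only the 6 libraries (0.012). HY5 and PIF4 stood at −0.25 ± 0.09 (adjusted p = 0.13) and −0.05 ± 0.12 (adjusted p = 0.83, with the sign turned without csu5-3 replicate 1 or 3). Leaving out a library moved the 48 calls to 11 without Col replicate 1, 27 without Col replicate 3, 29 without csu5-3 replicate 1 and 20 without csu5-3 replicate 2.

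**Figure D2:**
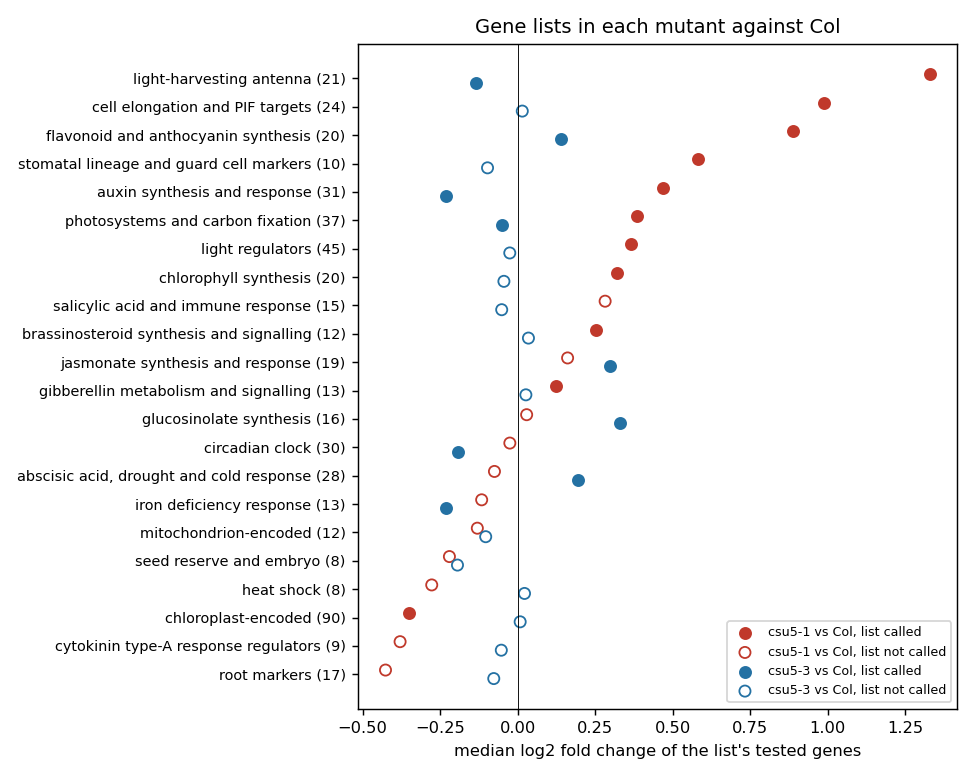
Median log2 fold change of each of the 22 gene lists in csu5-1 and in csu5-3 against Col, with filled points for lists called by camera at a preset correlation. The antenna median was 1.33 in csu5-1 and −0.13 in csu5-3; the medians of the photosystems and carbon fixation list turned to −0.08 and 0.01 under quantile normalization, and no list was called with an estimated correlation (lowest adjusted p = 0.081).

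The comparison of csu5-1 with csu5-3 tested the difference between the alleles itself. The antenna, elongation and auxin lists stood higher in csu5-1 than in csu5-3 (adjusted p = 0.081, 0.081 and 0.087 with an estimated correlation). PORA was at 125 ± 15.6 FPKM in csu5-1 and 0.547 ± 0.262 in csu5-3 (log2 difference 7.0 ± 0.19, adjusted p = 1.4e-10), and FAR1 (AT5G22500), a reductase of wax and suberin synthesis, at 80.1 ± 12.3 and 5.03 ± 0.431 FPKM. LOX2 (AT3G45140), a chloroplast lipoxygenase of jasmonate synthesis, was lower in csu5-1 (1.18 ± 1.01 against 16.1 ± 2.88 FPKM), as were CNX5 (AT5G55130), of molybdenum cofactor synthesis, and CT-BMY (AT4G17090), a starch-degrading beta-amylase (10 ± 0.606 against 82.2 ± 9.28 FPKM). In all, 1569 genes were higher and 1273 lower in csu5-1 (1300 and 1689 without scaling), and 2277 of the 3125 genes called in csu5-1 against Col (72.9%) were called here in the same direction. Both comparisons use the same csu5-1 libraries, so this share is not separate support for the calls against Col.

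By list, 17 of 21 antenna genes were higher and 0 lower in csu5-1 (1 lower at an unadjusted p below 0.05 in limma; 17 and 0 adjusted over the list alone), with a median of 1.43 (adjusted p = 1.3e-15, adjusted p = 0.081 with an estimated correlation). Of 31 auxin genes 19 were higher (19 adjusted over the list alone), with SAUR19 at 2.5 ± 0.16 and a median of 0.89 (adjusted p = 1.1e-10, adjusted p = 0.087 with an estimated correlation). Of 24 elongation genes 18 were higher (20 adjusted over the list alone), with PRE6 at 2.83 ± 0.10 and a median of 1.02 (adjusted p = 8.3e-10, adjusted p = 0.081 with an estimated correlation). Of 10 stomatal genes 6 were higher (7 adjusted over the list alone; median 0.84, adjusted p = 0.00087, adjusted p = 0.082 with an estimated correlation), among them MYB60 (AT1G08810, 0.67 ± 0.10, not called after removal of exon length and GC trends, 0.58). Light regulators had 15 of 45 higher and 1 lower (15 and 1 adjusted over the list alone; median 0.36, adjusted p = 1.7e-05, adjusted p = 0.081 with an estimated correlation), with PIF5 at 2.32 ± 0.08 and BBX28 at 2.88 ± 0.14. Flavonoid genes had 11 of 20 higher and 1 lower (11 and 1 adjusted over the list alone; median 0.84, adjusted p = 0.00015, adjusted p = 0.14 with an estimated correlation), with LDOX (AT4G22880) at 3.11 ± 0.24. Without csu5-1 replicate 1, 2 or 3 the flavonoid list's adjusted p was 0.24, 0.21 and 0.21.

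Chlorophyll synthesis had 7 of 20 higher and 2 lower (7 and 2 adjusted over the list alone; median 0.34, adjusted p = 0.00072, adjusted p = 0.39 with an estimated correlation), with HEMA1 (AT1G58290) at 0.95 ± 0.06. The photosystems list had 12 of 37 higher and 1 lower (12 and 1 adjusted over the list alone; median 0.46, adjusted p = 1e-06, adjusted p = 0.33 with an estimated correlation), turned to a median of −0.10 (adjusted p = 0.89) by quantile normalization. Gibberellin genes had 4 of 13 higher (4 adjusted over the list alone; median 0.11, adjusted p = 0.019, adjusted p = 0.14 with an estimated correlation, and 0.052 without csu5-1 replicate 3), with GA20OX1 (AT4G25420) at 1.56 ± 0.22. Of 90 chloroplast-encoded genes 13 were lower (6 adjusted over the list alone; median −0.36, adjusted p = 0.0073, adjusted p = 0.60 with an estimated correlation, and 0.071 without csu5-3 replicate 3). The lists not called were abscisic acid (adjusted p = 0.052; 2 higher, 9 lower, COR15A at −1.28 ± 0.20), brassinosteroid (0.054), salicylic acid (0.068), root markers (0.086), cytokinin regulators (0.11), mitochondrion-encoded (0.19), seed reserve (0.22), heat shock (0.23), glucosinolate (0.24), the clock (0.53; median −0.03, mean 0.27, camera's direction up), iron deficiency (0.75) and jasmonate (0.87; median −0.04, mean −0.09, camera's direction up).

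The series title's reversed action raised the question whether genes moved in opposite directions in the 2 mutants. Called against Col in both mutants were 19 genes in the same direction (11 higher, 8 lower) and 7 in opposite directions, of which 6 rose in csu5-1 and fell in csu5-3. LHCB1.1 was at 418 ± 35.9 FPKM in Col, 3060 ± 150 in csu5-1 and 211 ± 41.1 in csu5-3, and XTH25 (AT5G57550), a wall enzyme gene, at 3.68 ± 0.127, 12.2 ± 0.414 and 1.85 ± 0.139 FPKM. DIR1 and AT5G48490, neighbours in TAIR10.1 that both encode lipid-transfer proteins, rose in csu5-1 (1.06 ± 0.06 and 1.42 ± 0.06) and fell in csu5-3 (−0.84 ± 0.06 and −0.69 ± 0.06), as did SADHU3-2. Without Col replicate 1, XTH25 (adjusted p = 0.012), LHCB1.1 and SADHU3-2 were not called in csu5-3, and the opposite calls ranged from 3 to 9 over the left-out libraries. AT5G48490 was not called in csu5-3 without limma's trend (adjusted p = 0.011) or after removal of exon length and GC trends (−0.53). The same-direction calls fell from 19 to 5 without Col replicate 1, to 9 without Col replicate 3 or csu5-3 replicate 1 or 2, and to 11 without csu5-3 replicate 3. With no filter on low values 3 genes were called in the same and 2 in opposite directions, and without limma's trend 1 and 2. The replicate number as a block gave 33 and 13. With no filter the csu5-3 calls of LHCB1.1, XTH25, SADHU3-2, AT3G01345, BGLU18, AT1G52000, AT4G25580 and CP1 were lost, without the trend those of LHCB1.1, SADHU3-2, AT3G01345, BGLU18, AT1G52000 and CP1, and with only the 6 libraries that of XTH25. Among genes called in the same direction, AT3G01345 fell to 1.32 ± 0.995 FPKM in csu5-1 and 0.253 ± 0.15 in csu5-3 from 13.6 ± 5.19 in Col, BGLU18 rose to 32.3 ± 1.89 and 12.8 ± 4.34 FPKM, and AT1G52000 to 23.1 ± 2.42 and 27.2 ± 8.54 FPKM. CP1 rose and AT4G25580 fell in both, and CP1's call in csu5-3 was lost without any 1 library of Col or csu5-3 and without csu5-1 replicate 3 (adjusted p = 0.016 to 0.038).

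Independent lists of these sizes would share 1.91 higher and 1.96 lower genes and would hold 2.08 and 1.81 in the 2 opposite directions. Across the 19329 genes the fold changes of the 2 mutants had a covariance of 0.029, against 0.00882 ± 0.00028 (SD) in 100 simulations of unchanged mutants that share the Col libraries, an excess of 0.0201. Pearson's r across genes was 0.257 and Spearman's rho 0.308, and genes are not independent replicates. The simulated r of 0.501 is fixed by unchanged mutants sharing a control group of equal size. It is no reference for the observed r, since the fold changes spread unequally (SD 0.531 in csu5-1 and 0.212 in csu5-3). With 3 Col libraries the controls could not be split into 2 groups of 2, so part of the covariance excess may come from them. Taking all 3 genotypes at once, 7193 genes differed at an adjusted p below 0.01.

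**Figure D3:**
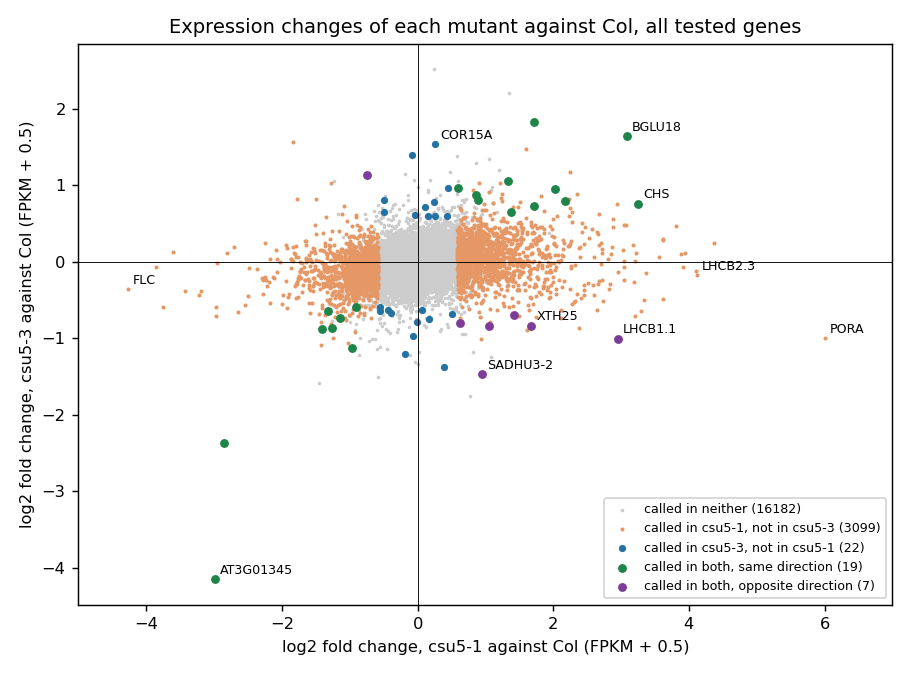
Log2 fold change in csu5-1 against Col (horizontal) and csu5-3 against Col (vertical) for each of 19329 tested genes, with colours for genes called in csu5-1 alone, csu5-3 alone, both in the same direction (19) or both in opposite directions (7). The points spread along the csu5-1 axis, where 3125 genes were called against 48 on the other.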

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

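Quantile normalization, limma without the trend and the removal of exon length and GC trends were chosen after the data were seen. The other tests in this part were chosen before their results were seen. The direct test of csu5-1 against csu5-3 asked which changes differed between the mutants, and 2842 genes did. The list medians (log2, csu5-1 minus csu5-3) were 1.43 for the light-harvesting antenna, 1.02 for cell elongation and PIF targets, 0.892 for auxin, 0.843 for flavonoids (8 of whose 20 genes passed the filter on low values through csu5-1 alone), 0.836 for the stomatal lineage and guard cells, 0.463 for the photosystems and carbon fixation (−0.0963 under quantile normalization), 0.356 for light regulators, 0.338 for chlorophyll synthesis, 0.112 for gibberellin and −0.358 for chloroplast-encoded genes. With an estimated correlation 0 of these 10 lists were called by camera (7 of the 22 lists tested had an unadjusted p below 0.05, with a lowest adjusted p of 0.081), and fry called 17 of 22, but not the chloroplast-encoded genes (adjusted p = 0.09).

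The 7 genes called in opposite directions against Col differ between the mutants by their selection, so the direct test adds only the size: LHCB1.1 by 3.96, XTH25 by 2.51, SADHU3-2 by 2.41, AT5G48490 by 2.11, DIR1 by 1.89, AT5G05965 by 1.43 and CORI3 by −1.88 on the log2 scale. LHCB1.1 encodes an antenna protein and XTH25 a wall-loosening enzyme, both higher in csu5-1 and lower in csu5-3 than in Col. AT5G05965 was not called in csu5-3 without Col replicate 1, 2 or 3 or csu5-3 replicate 1 or 2 (adjusted p = 0.012, 0.013, 0.017, 0.016 and 0.02), nor with no filter (0.023), only the 6 libraries (0.015), no trend in limma (0.025) or length and GC trends removed (0.017), and in csu5-1 it fell below the fold threshold without Col replicate 1 or without scaling (log2 fold 0.56 in each). CORI3, a jasmonate-induced gene, went the other way, at 1.44 ± 0.161 FPKM in csu5-1, 2.92 ± 0.535 in Col and 6.99 ± 0.996 in csu5-3 (n = 3 each), and lost its call in csu5-3 without Col replicate 1 or 3 or csu5-3 replicate 1 or 2 (adjusted p = 0.018, 0.012, 0.016 and 0.019), with no filter (0.021) and without limma's trend (0.02).

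The number of changed genes differed between the mutants, 3125 in csu5-1 against 48 in csu5-3. Exon length or GC content bias is argued against: with each library's trend removed, 3023 genes were called in csu5-1 and 41 in csu5-3. Low depth is argued against by estimated depths of 37.2 to 39.7 M counted reads in csu5-1, 39.4 to 42.0 M in Col and 39.1 to 43.1 M in csu5-3. By level, 14.8% of the 10895 genes with a mean of 10 FPKM or more were called, near the 18% of the 8434 lower genes. At least 2863 genes were called with any 1 library of csu5-1 or Col left out, so the calls do not hang on 1 library. A mislabelled or mixed library would add spread and cost calls, so this count cannot exclude one. On the first principal component the csu5-1 libraries lay at 45.7 to 49.1, and those of Col and csu5-3 at −26.1 to −22. The second put Col at 9.88 to 20.1 and csu5-3 at −17.7 to −11.5. These positions argue against a library swapped between genotypes. They do not exclude a slight mixture. The difference between the alleles and other genetic differences between the lines may each be the cause, were not tested, and cannot be separated in this design. The labels do not say that replicates came from separate cultures, and no hour of collection is given. Culture and hour of collection therefore cannot be separated from genotype either.

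In the splits of 6 libraries into 3 and 3, the real split called 3096 genes for csu5-1 against Col and the highest other split 0, with limma on the 6 libraries. For csu5-3 against Col the values were 35 and 1, and for csu5-1 against csu5-3 they were 2803 and 1. In each comparison 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. For the 3 genotypes together, 1 of 100 splits drawn from 280, the real one with 7193 genes, gave as many. That share argues against a random split of these libraries. It does not bear on genotype if the libraries of a genotype came from 1 culture, which the labels leave open. Of the 99 other drawn splits 0 kept the Col libraries together. The highest other split gave 5360 genes and was 1 of the 2 that kept the csu5-1 libraries together. The 4 that kept csu5-3 together gave 0 and those that kept no genotype together at most 1, so the csu5-1 libraries are the structure behind most of that count.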

How the results depend on the processing

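Pseudocounts, quantile normalization, limma without the trend and the removal of exon length and GC trends were chosen after the data were seen. Among the named genes that were called, PORA, LHCB2.1, FLC, CCA1, LHY and PIF4 in csu5-1 kept their calls in all alternatives run for single genes. Over 232 such results and 4586 combinations with an alternative, 4392 kept their call and 194 lost it. That count pools the 3 comparisons and does not describe the csu5-3 calls. Among all tested genes these went from 48 to 9 with no filter, 5 without limma's trend and 11 without Col replicate 1. Over 30 called lists, 505 of 570 combinations kept the call, 62 lost it and 3 reversed. With no filter 9 genes were called in csu5-3 (3 higher, 6 lower), 3 in both mutants in the same direction and 2 in opposite directions. At an adjusted p under 0.05 with no fold threshold the counts were 9618 (4733 higher, 4885 lower) in csu5-1, 999 (400, 599) in csu5-3, 8816 (4318, 4498) in the direct comparison, 583 same and 162 opposite. At a fold above 2 they were 1069 (649, 420), 13 (6, 7), 1009 (650, 359), 5 same and 1 opposite. With limma's treat against a fold of 1.5 they were 810 (503, 307), 1 (0, 1; 23 and 26 at an unadjusted p below 0.05), 763 (493, 270), 1 same and 0 opposite (8 at an unadjusted p below 0.05). Fits to the 6 libraries compared gave 14 higher in csu5-3. Limma without the trend gave 5 (1, 4) in csu5-3, 1 same and 2 opposite. A pseudocount of 0.1 gave a covariance of 0.0378. Thresholds change the counts by construction, and the cause of the others was not tested. Camera with an estimated correlation called 0, 0 and 0 lists (7, 3 and 7 at an unadjusted p below 0.05), and fry 19, 9 and 17. By fry the lists of abscisic acid (adjusted p = 0.061), photosystems (0.12) and flavonoids (0.074) in csu5-3 and the chloroplast-encoded genes in csu5-1 (0.075) and in the direct comparison (0.09) were not called.

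With the replicate number as a block, 77 genes were called in csu5-3 (43 lower), 33 same and 13 opposite. Same-number libraries correlated above 0.1 in 2 of 9 pairs (0.017 to 0.15), and the numbers were not taken as pairing. As a hint from the data that they may pair, all 9 of these correlations were above 0 against 2 of 18 between other numbers, and 7 of 9 libraries correlated best with their own number. With 1 library left out, the calls ranged from 2863 to 3129 in csu5-1 (1443 to 1607 higher, 1402 to 1522 lower), from 11 (without Col replicate 1) to 51 in csu5-3 (4 to 25, 7 to 26; 27 without Col replicate 3, 29 without csu5-3 replicate 1, 20 without csu5-3 replicate 2) and from 2579 to 2830 in the direct comparison (1405 to 1572, 1132 to 1263). Genes called in both ranged from 5 to 20 same and 3 to 9 opposite, the genotype test from 5596 to 6623, the covariance from 0.0269 to 0.037, and the lists called from 9 to 11, 8 to 10 and 9 to 12. Values that reversed were COP1 in csu5-1 against csu5-3 without scaling (−0.01171), COP1 in csu5-3 without csu5-3 replicate 3 (−0.01056) and with length and GC trends removed (−0.01316), PIF4 in csu5-3 without csu5-3 replicate 1 (0.002421) or 3 (0.05408), and AT1G52000 in the direct comparison without csu5-3 replicate 2 (0.1207), none of them called. Over the left-out libraries these ranged from −0.2211 to 0.05408 (PIF4), −0.01056 to 0.07345 (COP1 in csu5-3) and −0.2613 to 0.1207 (AT1G52000). The photosystems list reversed under quantile normalization (−0.0843 in csu5-1, 0.0149 in csu5-3, −0.0963 direct), and the cause was not tested. LHCB1.3 had a fold of 0 there by construction. Depth sets 1 read on 1 kilobase at 0.0232 to 0.0269 FPKM, so values near that, such as DFR in Col, rest on few reads. The 2 planned count-based alternatives were not run because the values are not counts.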

Other observations

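Product families of the annotation were tested after the data were seen. The draws of library residuals and of csu5-3 effects were chosen after an earlier simulation was seen. Quantile normalization, a pseudocount of 0.1, limma without the trend and the removal of exon length and GC trends were chosen after the data were seen. The other tests of the 2 patterns below were chosen before their results were seen. Of 175 families tested in each mutant by camera at a preset correlation, 13 passed an adjusted p of 0.05 in csu5-1 (3 up, 10 down) and 18 in csu5-3 (8 up, 10 down). With an estimated correlation 0 passed in either (13 and 19 at an unadjusted p below 0.05). Of 10 proline-rich extensin-like genes, structural proteins of the root and root-hair wall, 0 rose (0 at an unadjusted p below 0.05 in limma) and 8 fell, with a median log2 fold of −0.87 (adjusted p = 0.00076, adjusted p = 0.57 with an estimated correlation). In csu5-3 their median was −0.29 with 0 called by limma (3 lower at an unadjusted p below 0.05; adjusted p = 0.031, adjusted p = 0.59 with an estimated correlation). The root markers, of which 7 of 17 fell and 1 rose in csu5-1, were not called as a list by camera (adjusted p = 0.085) and were by fry (adjusted p = 0.001). Fry called 19 of the 22 lists in csu5-1, so its call does not single out the root markers. Of 43 thioredoxin superfamily genes 2 rose and 14 fell (median −0.41, adjusted p = 0.0002, adjusted p = 0.51 with an estimated correlation). They include AT4G15660, AT4G15670, AT4G15680, AT4G15690 and AT4G15700, 5 neighbours in TAIR10.1 that fell by 2.65 to 3.75 on the log2 scale and can share reads. Of 11 ribosomal protein genes of the L7Ae/L30e family 0 rose (0 at an unadjusted p below 0.05 in limma) and 5 fell (median −0.50, adjusted p = 0.0002, adjusted p = 0.51 with an estimated correlation), and of 22 leucine-rich receptor-like kinases 4 rose and 0 fell (1 lower at an unadjusted p below 0.05 in limma; median 0.34, adjusted p = 0.0002, adjusted p = 0.51 with an estimated correlation). Of 41 GDSL lipase genes 14 rose and 1 fell (median 0.28, adjusted p = 0.0002, adjusted p = 0.51 with an estimated correlation). These families were not particular to csu5-1. In csu5-3 the medians were −0.156 for thioredoxins (camera adjusted p = 0.0076), −0.145 for L7Ae/L30e (0.022), 0.126 for the receptor-like kinases (0.0019) and 0.105 for lipases (0.05). With an estimated correlation these adjusted p were 0.51 to 0.59. Both mutants were compared with the same Col libraries.

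The SAUR and histone families were lower in csu5-3 than in Col by camera at a preset correlation. Of 57 SAUR genes, small auxin-induced growth genes, 0 were called by limma (17 lower and 1 higher at an unadjusted p below 0.05), with a median of −0.25 (adjusted p = 0.0002, adjusted p = 0.51 with an estimated correlation). In csu5-1, 24 of the 57 SAUR genes rose and 7 fell, with a median of 0.44 (adjusted p = 0.068). Of 29 histone genes 0 were called by limma (9 lower at an unadjusted p below 0.05), with a median of −0.18 (adjusted p = 0.0002, adjusted p = 0.59 with an estimated correlation). Of 87 leucine-rich repeat kinases 0 were called by limma (21 higher and 1 lower at an unadjusted p below 0.05), with a median of 0.11 (adjusted p = 0.00022, adjusted p = 0.51 with an estimated correlation). In csu5-1, 8 of these kinases rose and 1 fell, with a median of 0.198 (camera adjusted p = 0.0072, adjusted p = 0.51 with an estimated correlation). The histone median in csu5-1 was 0.15, on the other side of its csu5-3 value. The signs of the extensin-like, thioredoxin, L7Ae/L30e, lipase, SAUR and histone medians held under trimmed-mean, median-ratio, no scaling and quantile normalization.

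The LHCB1 copies changed in opposite directions in csu5-1, and their levels became more even. LHCB1.3 supplied 78.4 ± 1.7% of the summed FPKM of 5 copies in Col, 45.6 ± 0.96% in csu5-1 and 78.8 ± 2.2% in csu5-3 (n = 3 each), while the sum was 49432 ± 591.9, 52760.5 ± 1189 and 47467.4 ± 2174 FPKM. The rises of LHCB1.1, LHCB1.2, LHCB1.4 and LHCB1.5 were 2.95, 2.11, 1.17 and 1.49 on the log2 scale (LHCB1.4 was not called under quantile normalization, 0.53), and the fall of LHCB1.3 lost its call without csu5-1 replicate 1 (adjusted p = 0.01), with no filter (0.30), with length and GC trends removed (−0.56) and, by construction, under quantile normalization (0). Reads that cannot be told apart between the copies are argued against, since 96.7% of the 100-base windows of LHCB1.3 occur in no other copy (83% of 50-base windows). A different control of LHCB1.3 in csu5-1 may be the cause, which was not tested.

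Genes moving the same way in both mutants numbered 19, but 5 without Col replicate 1, 9 without Col replicate 3 or csu5-3 replicate 1 or 2, and 11 without csu5-3 replicate 3. The lectin gene AT1G52000 and the beta-glucosidase BGLU18 rose in both (neither was called in csu5-3 with no filter or without limma's trend), and the defensin-like AT1G13609, chosen after its values were seen, fell from 3.7 ± 1.5 FPKM to 0.0467 ± 0.0808 in csu5-1 and 0.307 ± 0.272 in csu5-3 (not called in csu5-3 without csu5-3 replicate 1, adjusted p = 0.01, with no filter, 0.018, with a pseudocount of 0.1, 0.017, or without limma's trend, 0.027). Chance values of the shared Col libraries stay open, since no simulation had calls in csu5-3 near the observed 48. With csu5-3 unchanged it had at most 1 call, and at most 0 shared genes with independent noise or 1 with the libraries' own residuals dealt anew. With its fitted effects dealt to other genes of similar level it had 114 to 425 calls, and 82 of 100 draws shared 19 genes or more. Of the observed csu5-3 calls 39.6% were shared in the same direction, against at most 24.5% in any of those draws, at unlike numbers of calls. The condition that the calls be near 48 was set after those draws were seen. A difference of the Col seedlings from both mutant lines that is not due to csu5 cannot be told apart from a shared effect of the mutations, because both comparisons share 1 Col group. Of the 19 genes 7 also differed between csu5-1 and csu5-3 and 12 were not called there, and neither count decides between these explanations.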
